A study of Mus musculus with 15 samples.

How the data were processed

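Gene expression was measured on 15 Affymetrix arrays of cells sorted from mouse bone marrow: CDPs (2 arrays per genotype) and Zbtb46-GFP+ c-Kit-intermediate cells (3 arrays per genotype) from WT, Batf3 KO and Id2 KO mice. Per the labels' protocols, cells were sorted on a FACSAria, RNA was purified on columns, and biotinylated cDNA was made from total RNA with an Affymetrix WT Pico kit. WT and Id2 KO cells are labelled as coming from chimeric mice and Batf3 KO cells from reporter mice, so host type is confounded with the Batf3 genotype. The deposited unit is intensity: linear probe set signal after RMA, per the submitters' processing notes, which name Affymetrix Expression Console and RMA without versions or settings. The values were never negative and reached 21042, so they were read as linear and log2 was taken first. The number of arrays limits the precision.

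Each array held 28853 probe sets. The annotation named 23410 of them, 21789 with a single gene symbol and 1621 with several, and 5443 were not in it. Probe sets with a single symbol were used, with 1 per gene (the highest mean signal), which gave 19938 genes. Of the single-symbol probe sets, 21698 were matched to a gene in the RefSeq table of the mouse genome, used for chromosome names and gene order and not for positions.

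Replicate 1 of each Zbtb46-GFP+ group was on another scale, for a reason the labels do not give. Their median signals were 23.8 to 24.1, against 100.8 to 112.1 on the other 12. Between these 3 arrays, 20689 probe sets (71.7%) were identical in WT and Batf3 KO, 17130 (59.4%) in WT and Id2 KO, 17411 (60.3%) in Batf3 KO and Id2 KO, and 15586 (54.0%) in all 3; other pairs of arrays shared at most 22. Correlations across genes were 0.966 to 0.996 within the 12 arrays, at least 0.986 within the 3, and 0.882 to 0.917 between the sets. All 15 arrays enter the fit as designed. The reported values come from the 12 arrays without those 3, and a further fit kept all 15 with a fixed term for the 3; these choices, and the repeat of each alternative on the 12 arrays, were made after seeing the data. The 3 arrays also gave a comparison of direction between single arrays, without a test.

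Comparisons used limma 3.58.1 in R 4.3.3 (statmod 1.5.0): a linear model of 6 group means, empirical Bayes without trend, two-sided, with Benjamini-Hochberg adjustment over all genes within each of 10 planned comparisons and an adjusted p under 0.05. These were the stage step in each genotype, each knockout against WT in each stage, Id2 KO against Batf3 KO in Zbtb46-GFP+ cells, and the interaction of each knockout with stage. The fit on 12 arrays has 6 residual degrees of freedom. The fit as designed, the comparisons, lists, naming rule and other alternatives were set before the data were examined. The procedure was tested on simulated data with 200 genes changed in Id2 KO Zbtb46-GFP+ arrays. Of these, 68 of 100 were called at a log2 change of 1 and 96 of 100 at 2, with 7 false calls among 171. Values were drawn independently for each gene and array, so these rates need not hold for the real arrays, whose residuals are correlated.

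The genes named are the targeted genes in every group and the regulators (Irf8, Irf4, Nfil3, Zeb2, Id2, Id3, Batf3, Tcf4, Zbtb46, Kit, Flt3 and Csf1r). Added to these are the called genes with the largest change whose groups do not overlap (10 in each direction for the WT step and the knockouts in Zbtb46-GFP+ cells, 5 elsewhere) and up to 4 called members per list. The rule was applied to the 12 arrays. Other genes named were chosen after their values were seen: Clec9a, Kcnma1, Prss34, Irf7 and Pld4 in Id2 KO, the neighbours of Batf3, the interactions of Tlr3, Gatm, Cd36, Xcr1, Ppt1, Fcrla, Rab7b, Igfbp4 and Clec9a outside the rule, the called genes of Batf3 KO with room to shift in CDPs, and genes shared by both knockouts. The 15 gene lists, written from general knowledge of the cell types, were cDC1, cDC2, pDC, lymphoid progenitor and B-lineage, haematopoietic progenitor, MHC class II and antigen processing, cell division, monocyte and macrophage, neutrophil and granule, erythroid and megakaryocyte, T, NK and innate lymphoid, interferon-stimulated, DC transcription factor, immediate early and stress, and sex-linked genes. They were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Batf3 was left out of lists in Batf3 KO comparisons and Id2 in Id2 KO comparisons. Of the list members, 24 were not measured. After a first run, the matching of list members through older gene symbols was corrected where a listed symbol is itself a gene.

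Whether replicate numbers pair the arrays was checked from residual correlations. On 15 arrays they ran from 0.56 to 0.96 between Zbtb46-GFP+ arrays and from 0.53 to 0.68 between CDP arrays, so counts with the replicate number as a block are given where they change a count; the highest value is that of the 3 arrays on another scale. On the 12 arrays the WT Zbtb46-GFP+ numbers correlated at -0.55 and -0.42 with those of the knockouts. The 12 arrays were parted into 2 sets by the 75th percentile of signal within each group, so that each set holds 1 array of every group by construction. Residual correlations between groups had a median of 0.54 within a set (lowest 0.35) and -0.54 between. With 2 arrays per group the value between sets mirrors the value within a set by construction. The split on signal also favours such alignment, so these values do not show that the sets are real. The labels name no such sets, and a block defined from the values takes up part of the spread between replicates. Leave-one-out fits leave a group with 1 array, which is assumed to vary like the others. Alternatives were all probe sets, no dim genes (lowest 33.3%), quantile normalisation, centring on the 75th percentile, trend and robust variance, array weights, the replicate number as a fixed or random block, the compared groups alone, a log2 change of at least 1, and, added after seeing the data, the 2 sets as a block and no genes on X and Y. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6. Raw array images were not used here.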

Results

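Common dendritic cell progenitors (CDPs) give rise to plasmacytoid and classical dendritic cells (DCs), and Zbtb46, read out here by a GFP reporter, marks progenitors committed to the classical lineage. Batf3 is the AP-1 factor that maintains Irf8 expression in the cDC1 subset, and Id2 restrains the E proteins that drive plasmacytoid DC (pDC) fate. The question was which genes change along the step from CDP to Zbtb46-GFP+ c-Kit-intermediate cells, and how loss of Batf3 or of Id2 alters that step. Signal was measured on 15 arrays, with 2 CDP and 3 Zbtb46-GFP+ arrays for each of WT, Batf3 KO and Id2 KO. Replicate 1 of each Zbtb46-GFP+ group was on another scale, with median signals of 23.8 to 24.1 against 100.8 to 112.1 on the other 12 arrays. The reported values come from the 12 arrays on a common scale, 2 per group, a choice made after seeing the data. Each count is set beside those of the fit on all 15 arrays as designed and of the 15-array fit with a term for the 3 arrays. Within each group, 1 of the 2 arrays had the higher 75th percentile of signal, and these 2 sets of arrays, also defined after seeing the data, entered a further fit as a block.

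In the knockouts, the Batf3 probe set (10352717) stayed at its CDP level in Zbtb46-GFP+ cells that lacked Batf3, and the Id2 probe set (10399691) was lower without Id2. Batf3 measured 7.14 ± 0.02 log2 units (mean ± SD, n = 2) in WT CDPs and 9.92 ± 0.10 in WT Zbtb46-GFP+ cells. It was 7.11 ± 0.21 and 7.10 ± 0.31 in the Batf3 KO CDPs and Zbtb46-GFP+ cells. In the Id2 KO it was 7.05 ± 0.26 and 8.29 ± 0.11. Id2 measured 7.54 ± 0.19 in WT CDPs and 11.74 ± 0.37 in WT Zbtb46-GFP+ cells. It was 7.79 ± 0.05 and 11.35 ± 0.30 in the Batf3 KO, and 6.52 ± 0.79 and 8.61 ± 0.30 in the Id2 KO. The Id2 signal therefore still rose with stage in the Id2 KO (log2 fold change 2.09, SE 0.32, adjusted p = 0.00259), and whether its probes lie within the deleted part was not analysed here. The 12 arrays also differed in sex pattern: Xist differed by -6.61 and -6.53 log2 units in Batf3 KO and Id2 KO from WT Zbtb46-GFP+ cells. The Y-linked genes Kdm5d, Uty and Eif2s3y were higher. Sex pattern and genotype are therefore confounded in these 12 arrays, and counts are also given without genes on X and Y.

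**Figure D1:**
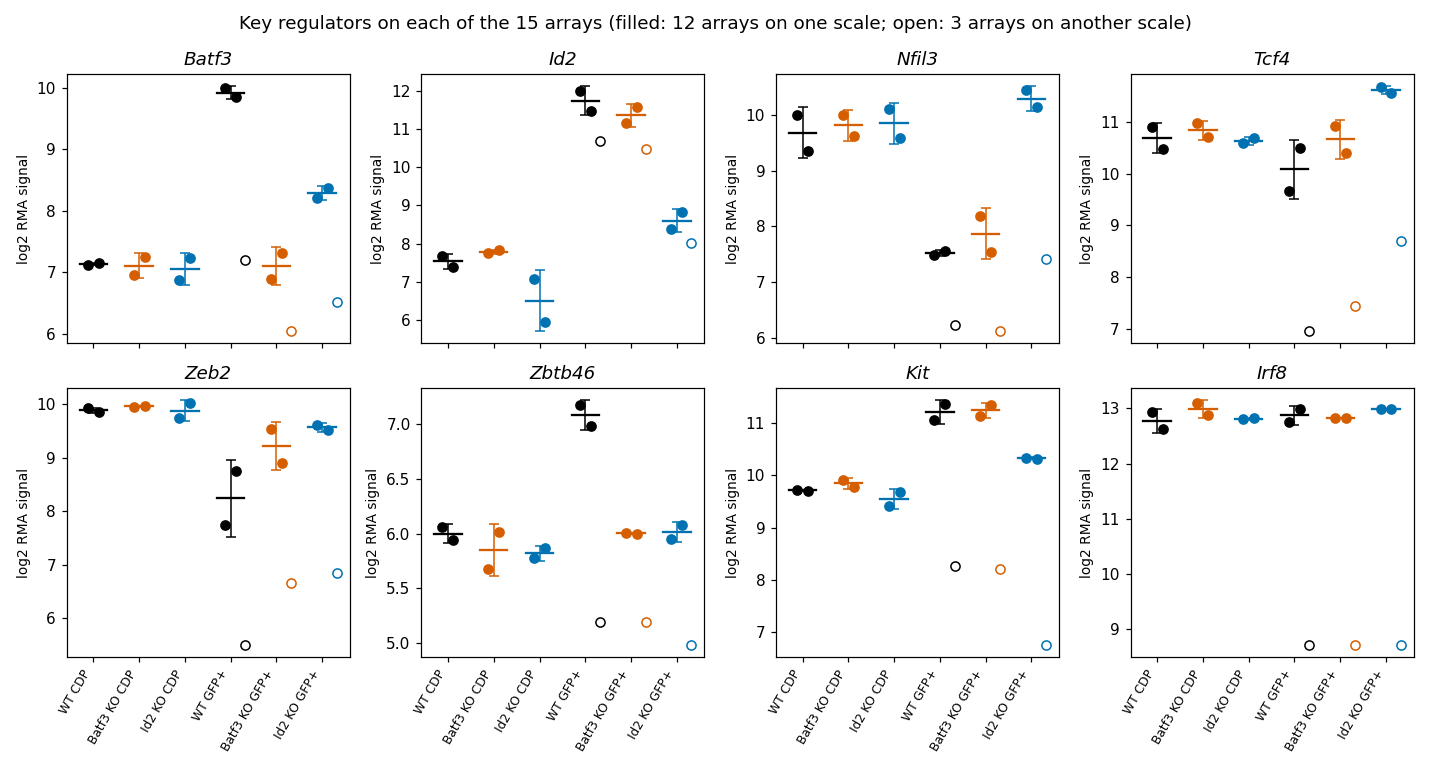
Log2 RMA signal of Batf3, Id2, Nfil3, Tcf4, Zeb2, Zbtb46, Kit and Irf8 on each array, by group; filled points are the 12 arrays on a common scale with their mean (line) and SD (error bar), and open points are the 3 arrays on another scale. Batf3 rose from CDP to Zbtb46-GFP+ cells in WT and Id2 KO but not in Batf3 KO, and Id2 was lowest in Id2 KO at each stage.

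From CDP to Zbtb46-GFP+ cells in WT, the antigen-presentation genes Cd74, H2-Aa, H2-Eb1 and H2-Ab1 rose, as did Tlr3, the sensor of double-stranded RNA used by cDC1s. Anpep, a surface peptidase, Plbd1, a phospholipase-like protein, and Slamf7 and Gpr141b, surface receptors, rose as well. The granule genes Mpo, Ctsg and Prtn3 fell, together with F13a1, a transglutaminase of monocytes, and Cd93, a receptor of early progenitors. Among regulators, Batf3, Id2, Irf4, Zbtb46 and Kit rose. The later cells were sorted on Zbtb46-GFP and c-Kit, so the rises of Zbtb46 and Kit may partly be set by the gate. Nfil3, a bZIP factor needed early in cDC1 development, Zeb2 and the M-CSF receptor gene Csf1r fell. Cd74 changed most among higher genes (log2 fold change 7.17, SE 0.20, adjusted p = 7.30e-09). H2-Aa followed at 6.48, Tlr3 at 6.11 and H2-Eb1 at 5.73. Next came Plbd1 at 5.66, Anpep at 5.59, Slamf7 at 5.57, H2-Ab1 at 5.52, Gpr141b at 5.45 and Ifi205 at 5.40. Mpo changed by -5.02, Ctsg by -4.71 and F13a1 by -4.13. Cd93 changed by -4.03, Prtn3 by -3.97 and Igfbp4 by -3.84. The adhesion G-protein-coupled receptor genes Adgrg3, Adgrl4 and Adgrg1 changed by -3.61, -3.59 and -3.27, and Rab44 by -3.32.

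Batf3 rose by 2.79 (SE 0.18, adjusted p = 4.76e-06) and Id2 by 4.19 (SE 0.32, adjusted p = 1.49e-05). Irf4 rose by 2.48 and Zbtb46 by 1.08, Kit rose 2.82-fold, and the log2 fold changes of Nfil3, Csf1r and Zeb2 were -2.16, -2.03 and -1.64. Irf8 (0.10), Flt3 (0.11), Id3 (0.77, adjusted p = 0.0604) and Tcf4 (-0.61, adjusted p = 0.189) did not pass the test; with the sets as a block, Id3 (adjusted p = 0.0132) and Tcf4 (0.0264) did. On the 12 arrays limma called 2212 genes, 940 higher and 1272 lower, at an adjusted p under 0.05. The direction split depended on scaling, with 1152 higher and 862 lower when each array was centred on its 75th percentile. Without WT CDP replicate 1 the count was 1180, and with the sets as a block 4828. Fitted as designed on 15 arrays, limma called 1 gene, Tlr3 (adjusted p = 0.0257), with 215 at an unadjusted p under 0.05 and 25 called with the replicate number as a block. The 15-array fit with a term for the 3 arrays called 2679 (1104 higher, 1575 lower). Of 61 named genes past the threshold, 55 kept their call with each array left out in turn and 59 with the 15-array term.

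The cDC1 genes, the list of markers of cross-presenting DCs, rose as a group, led by Tlr3, Ifi205, Naaa (4.84) and Id2. Antigen-presentation genes rose and haematopoietic progenitor genes fell. The cDC1 list had 21 of 25 members higher and 1 lower (adjusted over the list alone, 23 and 1). Its median was 2.30, with a camera adjusted p of 7.16e-30, and 0.00698 with an estimated correlation. The MHC class II and antigen processing list had 14 of 19 members higher and 1 lower (adjusted over the list alone, 15 and 1). Its camera adjusted p was 6.70e-19, and 0.0074 with an estimated correlation. Among progenitor genes, which include Mpo and the cyclin-dependent kinase gene Cdk6 (-2.62), there were 2 of 25 members higher and 15 lower (adjusted over the list alone, 2 and 15). For these genes camera gave an adjusted p of 8.81e-10, and 0.00698 with an estimated correlation. Immediate early and stress genes, among them Btg2 (1.92) and Zfp36 (1.45), had 6 of 19 members higher and 1 lower (adjusted over the list alone, 8 and 1) (camera adjusted p = 2.99e-04; 0.0228 with an estimated correlation).

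Several lists passed camera only at its preset correlation. The cDC2 list, led by Clec4b1 (4.64) and Cd209a (3.50), had 12 of 25 members higher and 3 lower (adjusted over the list alone, 13 and 4) (adjusted p = 0.265 with an estimated correlation). Interferon-stimulated genes, led by Mx1 (1.71), a restriction factor for viruses, with Gbp3 (-2.31) lower, had 12 of 20 members higher and 1 lower (adjusted over the list alone, 14 and 1) (adjusted p = 0.265 with an estimated correlation). Monocyte and macrophage genes, among them Fcgr4 (2.53), had 9 of 18 members higher and 2 lower (adjusted over the list alone, 11 and 3) (adjusted p = 0.226 with an estimated correlation). The replication licensing genes Mcm2 (-1.43), Mcm6 (-1.13) and Mcm3 (-1.12) fell, and the cell division list had 0 of 26 members higher and 8 lower (adjusted over the list alone, 0 and 11) (adjusted p = 0.226 with an estimated correlation). The T, NK and innate lymphoid list had 2 of 19 members higher and 0 lower (adjusted over the list alone, 2 and 0) (adjusted p = 0.333 with an estimated correlation). The erythroid and megakaryocyte list had 1 of 13 members higher and 0 lower (adjusted over the list alone, 1 and 0) (adjusted p = 0.386 with an estimated correlation), and its camera p rose to 0.172 without WT CDP replicate 1, 0.0907 without WT GFP+ replicate 2 and 0.0541 without WT GFP+ replicate 3. The pDC list had 4 of 22 members higher and 1 lower (adjusted over the list alone, 5 and 2), with Irf7 (2.79) and Ccr9 (2.25) higher and Tex2 (-1.50) lower, and did not pass camera (adjusted p = 0.678). The lymphoid progenitor list, with Vpreb1 (-2.15) and Dntt (-1.93) lower, also did not pass (adjusted p = 0.359), nor did the DC transcription factor list with 8 of 35 members higher and 5 lower (adjusted over the list alone, 11 and 8) (adjusted p = 0.253). The neutrophil and granule list had 0 of 18 members higher and 5 lower (adjusted over the list alone, 2 and 5) and did not pass (adjusted p = 0.645); its median (0.43) and its mean (-0.18) differed in sign. The sex-linked list had 0 called members (adjusted p = 0.645).

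The same step in the Batf3 KO kept the rise of the MHC class II genes H2-Aa, Cd74, H2-Eb1 and H2-Ab1 and the fall of Mpo and Ctsg, while Batf3 itself did not change. In the Id2 KO, H2-Aa and Cd74 again rose and Ctsg fell. The pDC genes Spib, an Ets factor, and Ccr9, a chemokine receptor, rose there beside Ly6d, a surface protein of lymphoid progenitors. Ccr9 rose in the Batf3 KO step (2.29) and the WT step (2.25) as well. In the limma interaction of Id2 KO with stage, Spib did not pass (adjusted p = 0.976), while Ly6d did (0.0197). In the Batf3 KO the log2 fold change of Batf3 was -0.00 and that of Id2 3.56. H2-Aa changed by 7.03, Cd74 by 6.94, Ctsg by -3.76 and Mpo by -3.15 (adjusted p = 0.0503 without Batf3 KO CDP replicate 1). The limma count was 1432 (771 higher, 661 lower). It was 638 without Batf3 KO CDP replicate 1, 757 without CDP replicate 2, 826 without GFP+ replicate 2 and 744 without GFP+ replicate 3. In the Id2 KO, Cd74 changed by 6.67, H2-Aa by 6.43, and Slamf7 by 4.79. Spib changed by 3.08 (adjusted p = 0.0555 without Id2 KO GFP+ replicate 2), Ccr9 by 2.98 and Ly6d by 2.72 (adjusted p = 0.078 with the 15-array term). Ctsg changed by -3.41 and Batf3 by 1.24. The Id2 KO count was 1358 (765 higher, 593 lower). It was 765 without Id2 KO CDP replicate 1, 488 without GFP+ replicate 2 and 632 without GFP+ replicate 3. As designed on 15 arrays, limma called 0 genes in each knockout (133 and 124 at an unadjusted p under 0.05; 3 and 0 called with the replicate number as a block). With the 15-array term the counts were 1918 and 1917, and on the 12 arrays with the sets as a block 3486 and 3231.

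Across lists, the cDC1 genes rose with stage in both knockouts, with Tlr3 at 3.79 in Batf3 KO and 2.21 in Id2 KO and Ifi205 at 2.49 and 3.29. In Batf3 KO there were 11 of 24 members higher and 1 lower (adjusted over the list alone, 13 and 1), with 0.0305 as camera's adjusted p with an estimated correlation. In Id2 KO there were 9 of 24 members higher and 0 lower (adjusted over the list alone, 12 and 0) (camera adjusted p = 5.96e-14; 0.0253 with an estimated correlation). MHC class II genes had 14 of 19 members higher and 0 lower (adjusted over the list alone, 15 and 0) in Batf3 KO (0.00655 with an estimated correlation) and 13 of 19 members higher and 0 lower (adjusted over the list alone, 15 and 0) in Id2 KO (0.009). Progenitor genes had 2 of 25 members higher and 11 lower (adjusted over the list alone, 2 and 14) in Batf3 KO (0.00655 with an estimated correlation) and 2 of 25 members higher and 10 lower (adjusted over the list alone, 2 and 12) in Id2 KO (0.0155). The pDC list had 14 of 22 members higher and 0 lower (adjusted over the list alone, 15 and 0) in Id2 KO (adjusted p = 0.12 with an estimated correlation). In Batf3 KO it had 5 of 22 members higher and 1 lower (adjusted over the list alone, 6 and 3) and did not pass camera (adjusted p = 0.283). The cDC2 list, with Cd209a at 3.96 and 3.58 and Irf4 at 3.39 and 3.21, had adjusted p = 0.102 and 0.12 with an estimated correlation in Batf3 KO and Id2 KO. Neutrophil genes had 8 of 18 members higher and 2 lower (adjusted over the list alone, 9 and 2) in Batf3 KO and 7 of 18 members higher and 2 lower (adjusted over the list alone, 9 and 3) in Id2 KO, with adjusted p = 0.475 and 0.503 with an estimated correlation. Interferon-stimulated genes had 11 of 20 members higher and 1 lower (adjusted over the list alone, 19 and 1) in Batf3 KO and 6 of 20 members higher and 1 lower (adjusted over the list alone, 13 and 1) in Id2 KO, with adjusted p = 0.0993 and 0.222 with an estimated correlation.

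In Batf3 KO Zbtb46-GFP+ cells, genes that characterise the cDC1 subset were lower than in WT: Xcr1, the receptor for Xcl1, Clec9a, which binds dead-cell actin, Tlr3 and the scavenger receptor gene Cd36. The orphan receptor gene Gpr141b, the Ras activator gene Rasgrp3, and Gcsam and Snx22, a signalling adaptor and a sorting nexin, were lower too. Gatm, an enzyme of creatine synthesis, also fell. The autosomal genes that were higher included Hpgd, which degrades prostaglandins, the interferon-inducible gene Ifi202b and the lectin gene Cd209e. Batf3 changed by -2.82 (SE 0.18, adjusted p = 2.13e-05) and by -1.15 in the replicate 1 arrays. Gpr141b changed most outside the sex-linked genes (log2 fold change -4.48, SE 0.30, adjusted p = 3.03e-05). Rasgrp3 changed by -3.75, Gcsam by -3.63, and Cd36 by -3.61. Clec9a changed by -1.01 (adjusted p = 0.0096; 0.0777 without WT GFP+ replicate 3, 0.129 without Batf3 KO GFP+ replicate 2 and 0.0833 without Batf3 KO GFP+ replicate 3). Xcr1 changed by -3.23, Snx22 by -3.19 (adjusted p = 0.263 with the 15-array term), Gatm by -2.31 and Tlr3 by -2.23. Hpgd changed by 2.81, Lipo3 by 2.27, Ifi202b by 1.96 and Cd209e by 1.80 (adjusted p = 0.248 with the 15-array term). In the replicate 1 arrays, one per genotype, Gpr141b differed by -3.56, Cd36 by -2.48, Lipo3 by 2.28, Gcsam by -2.14 and Ifi202b by 1.85. Xcr1 differed there by -1.72, Gatm by -1.47, Tlr3 by -1.37, Rasgrp3 by -1.21, Hpgd by 1.00 and Snx22 by -0.11. Cd209e and Zbtb46 were tied there, with a difference of 0.

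Zbtb46 fell by 1.08 (adjusted p = 0.00713), with adjusted p = 0.0896 without Batf3 KO GFP+ replicate 2 and 0.0758 without Batf3 KO GFP+ replicate 3, and 0.383 with the 15-array term. Its mean log2 signal was 6.002 in Batf3 KO Zbtb46-GFP+ cells, the level of WT CDPs (6.002), against 7.08 in WT Zbtb46-GFP+ cells. These cells were sorted on the Zbtb46 reporter, so what this lower signal means for the gene stays open. Other regulators did not pass: Id2 -0.38, Irf8 -0.05, Irf4 1.02 (adjusted p = 0.614), Zeb2 0.98 (adjusted p = 0.446), Nfil3 0.34, Tcf4 0.58, Id3 -0.58, Csf1r 0.68, Kit 0.03 and Flt3 -0.10. The limma count was 67 (22 higher, 45 lower), of which 60 lay outside X and Y (18 higher, 42 lower). It was 33 without Batf3 KO GFP+ replicate 2 and 39 without replicate 3, and 249 (135 higher, 114 lower) with the sets as a block. The fit as designed on 15 arrays gave 0 limma calls (11 at an unadjusted p under 0.05; 1 called with the replicate number as a block), and the 15-array term gave 29 (10 higher, 19 lower). Of 37 named genes past the threshold, 20 kept their call with each array left out and 17 with the 15-array term. Those that lost it with the term include Xist, Kdm5d, Uty and Eif2s3y, since Batf3 KO replicate 1 had the WT sex pattern. Of the 60 called genes outside X and Y, 19 had identical values in the replicate 1 pair. Among the 41 that were not tied, 40 differed in the same direction there (97.6%), against 55.8% of all untied genes. Over all 60 genes, with the 19 tied ones at 0, the median difference in that direction was 0.34 in the replicate 1 pair. On the 12 arrays it was 1.499.

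The cDC1 list fell as a group, with 0 of 24 members higher and 12 lower (adjusted over the list alone, 0 and 15). Its median was -1.02, and its camera adjusted p 6.62e-46, or 0.00267 with an estimated correlation. Neutrophil and granule genes, which mark another lineage, moved the other way: Prtn3 changed by 1.44 (adjusted p = 0.144 without Batf3 KO GFP+ replicate 2 and 0.155 without Batf3 KO GFP+ replicate 3) and Csf3r by 1.11 (adjusted p = 0.122 without WT GFP+ replicate 3 and 0.249 without Batf3 KO GFP+ replicate 2). That list had 2 of 18 members higher and 0 lower (adjusted over the list alone, 6 and 0) (adjusted p = 0.133 with an estimated correlation). The pDC list had 1 of 22 members higher and 0 lower (adjusted over the list alone, 1 and 0) (adjusted p = 0.133 with an estimated correlation). Interferon-stimulated genes had 0 of 20 members higher and 0 lower (adjusted over the list alone, 3 and 0) (adjusted p = 0.133 with an estimated correlation). The cDC2 list had 1 of 25 members higher and 0 lower (adjusted over the list alone, 7 and 1) (adjusted p = 0.133 with an estimated correlation; camera adjusted p = 0.0907 without WT GFP+ replicate 2). Progenitor genes had 0 of 25 members higher and 0 lower (adjusted over the list alone, 3 and 0) (adjusted p = 0.104 with an estimated correlation). The lymphoid progenitor list had no called member and adjusted p = 0.106 with an estimated correlation (camera adjusted p = 0.0519 without WT GFP+ replicate 2, 0.116 without WT GFP+ replicate 3 and 0.0544 without Batf3 KO GFP+ replicate 3). The cell division list had none either, and adjusted p = 0.466 with an estimated correlation (camera adjusted p = 0.69 without WT GFP+ replicate 3 and 0.288 without Batf3 KO GFP+ replicate 2). Monocyte and macrophage genes, with Adgre1 at 1.56 (adjusted p = 0.112 without WT GFP+ replicate 2 and 0.204 without Batf3 KO GFP+ replicate 2) and F13a1 at 1.09 (adjusted p = 0.139 without WT GFP+ replicate 2, 0.0777 without WT GFP+ replicate 3 and 0.269 without Batf3 KO GFP+ replicate 2), did not pass camera (adjusted p = 0.0718). Nor did MHC class II genes (0.444), DC transcription factors (0.0694; 0.0252 with the sets as a block), erythroid genes (0.0715), T and NK genes (0.0537) or stress genes (0.665). The sex-linked list passed (0.0284 with an estimated correlation).

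**Figure D2:**
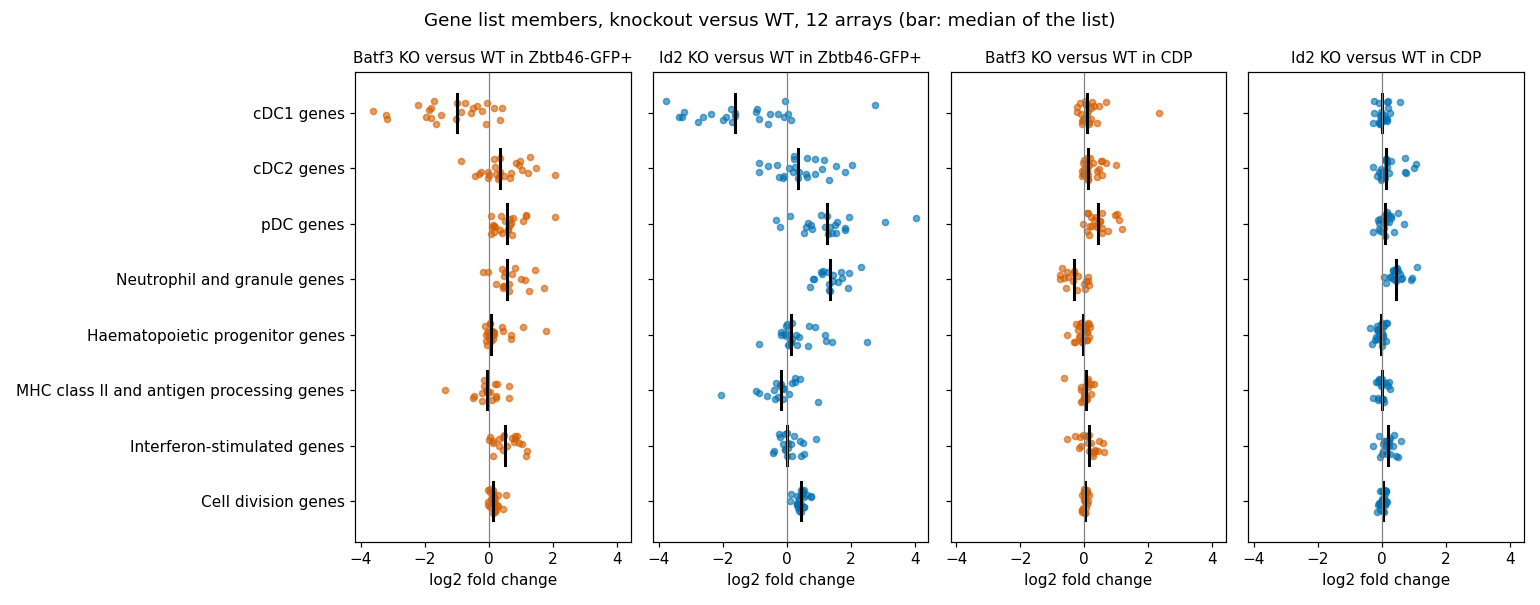
Log2 fold change of each member of the cDC1, cDC2, pDC, neutrophil, progenitor, MHC class II, interferon-stimulated and cell division lists, for Batf3 KO and Id2 KO against WT, in Zbtb46-GFP+ cells and in CDPs (12 arrays; each point a gene, each bar the list median). The cDC1 medians lie at -1.02 and -1.63 in Zbtb46-GFP+ cells, and the pDC medians at 0.55 and 1.27.

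In Id2 KO Zbtb46-GFP+ cells many of the same genes were lower than in WT, among them Gpr141b, Tlr3, Rasgrp3, Gcsam, Snx22, Xcr1, Cd36 and Anpep, as was Batf3. Genes of pDCs and lymphoid progenitors rose instead: Ly6d, Siglech, the sialic acid receptor of pDCs, Blnk, a B-cell adaptor, and Tcf4, the E protein that drives pDC identity. Nfil3 and the adhesion gene Cdh1 rose as well. Myb, a factor of early progenitors, and the granule genes Elane, Ms4a3 and Prtn3 were also higher. Id2 changed by -3.13 (SE 0.32, adjusted p = 5.05e-04) and by -2.66 in the replicate 1 arrays, and Batf3 by -1.63 (SE 0.18, adjusted p = 9.64e-04). Nfil3 changed by 2.77 (adjusted p = 3.86e-04) and Zbtb46 by -1.06 (adjusted p = 0.00336; 0.0794 with the 15-array term). The mean log2 signal of Zbtb46 was 6.02 in Id2 KO Zbtb46-GFP+ cells, near that of WT CDPs (6.002), although the cells were sorted on its reporter. Tcf4 rose by 1.54 (adjusted p = 0.0116; 0.0544 without WT GFP+ replicate 2, 0.117 without Id2 KO GFP+ replicate 2 and 0.0879 without Id2 KO GFP+ replicate 3). Zeb2, a repressor that favours pDCs, rose by 1.32 (adjusted p = 0.0443; 0.179 without WT GFP+ replicate 2, 0.316 without Id2 KO GFP+ replicate 2 and 0.21 without Id2 KO GFP+ replicate 3). Csf1r rose by 1.15 (adjusted p = 0.0239; 0.146 without WT GFP+ replicate 2, 0.137 without Id2 KO GFP+ replicate 2 and 0.204 without Id2 KO GFP+ replicate 3). Kit fell by 0.88 (adjusted p = 0.0131; 0.0877 without WT GFP+ replicate 3, 0.116 without Id2 KO GFP+ replicate 2 and 0.124 without Id2 KO GFP+ replicate 3). Irf8 (0.12), Irf4 (0.64), Id3 (-0.40) and Flt3 (0.16) did not pass.

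Gpr141b changed by -4.55, Tlr3 by -3.78 (SE 0.14, adjusted p = 1.78e-07), Rasgrp3 by -3.42 and Gcsam by -3.37. Snx22 changed by -3.27 (adjusted p = 0.0683 with the 15-array term), Xcr1 by -3.22, Cd36 by -3.08 and Anpep by -3.04. Among higher genes, Ly6d changed by 4.03 (adjusted p = 3.86e-04) and Cdh1 by 2.61. Siglech changed by 3.06 (adjusted p = 0.00641; 0.0645 without Id2 KO GFP+ replicate 2 and 0.0618 without Id2 KO GFP+ replicate 3) and Mctp2 by 3.01 (0.0636 without WT GFP+ replicate 2, 0.107 without Id2 KO GFP+ replicate 2 and 0.0652 without Id2 KO GFP+ replicate 3). The limma count was 361 (218 higher, 143 lower), of which 338 lay outside X and Y (205 higher, 133 lower). It was 139 without Id2 KO GFP+ replicate 2 and 120 without replicate 3, and 1211 (817 higher, 394 lower) with the sets as a block. The limma fit as designed gave 0 calls on 15 arrays (37 at an unadjusted p under 0.05; 2 called with the replicate number as a block), and the 15-array term gave 206 (103 higher, 103 lower). Of 53 named genes past the threshold, 27 kept their call with each array left out and 39 with the 15-array term. Of 338 called genes outside X and Y, 102 had identical values in the replicate 1 pair, and of the 236 that were not tied, 226 differed in the same direction there (95.8%), against 51.0% of all untied genes. Over all 338 genes, with the 102 tied ones at 0, the median difference in that direction was 0.25 there and 1.17 on the 12 arrays.

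By list, cDC1 genes fell and pDC and neutrophil genes rose. The cDC1 list had 1 of 24 members higher and 15 lower (adjusted over the list alone, 1 and 17) and the member that rose was Nfil3. Its median was -1.63 and its camera adjusted p 4.81e-32, or 0.00799 with an estimated correlation. The pDC list, led by Ly6d and Siglech and with Tex2 at 1.83, had 10 of 22 members higher and 0 lower (adjusted over the list alone, 19 and 1). The median pDC member changed by 1.27, with a camera adjusted p of 1.43e-23, or 0.0408 with an estimated correlation. The neutrophil and granule list had 6 of 18 members higher and 0 lower (adjusted over the list alone, 12 and 0). The median neutrophil gene changed by 1.35, with a camera adjusted p of 1.09e-18, or 0.0403 with an estimated correlation. Its member Prtn3 changed by 1.90, Elane by 2.32 (0.0538 without Id2 KO GFP+ replicate 3) and Ms4a3 by 1.95 (0.113 without WT GFP+ replicate 3, 0.116 without Id2 KO GFP+ replicate 2 and 0.139 without Id2 KO GFP+ replicate 3). Progenitor genes, with Myb at 1.21, had 4 of 25 members higher and 1 lower (adjusted over the list alone, 7 and 1) (0.0343 with an estimated correlation). Lymphoid progenitor genes, with Blnk at 1.98 (0.131 without WT GFP+ replicate 2, 0.217 without Id2 KO GFP+ replicate 2 and 0.0937 without Id2 KO GFP+ replicate 3), had 1 of 24 members higher and 0 lower (adjusted over the list alone, 2 and 0) (0.0366 with an estimated correlation). Stress genes fell, with 0 of 19 members higher and 1 lower (adjusted over the list alone, 0 and 4), a median of -0.26 and 0.03 with an estimated correlation. Cell division genes had 0 of 26 members higher and 0 lower (adjusted over the list alone, 3 and 0) and a median of 0.44 (adjusted p = 0.0741 with an estimated correlation).

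The cDC2 list had 4 of 25 members higher and 1 lower (adjusted over the list alone, 9 and 2) (adjusted p = 0.256 with an estimated correlation; camera adjusted p = 0.231 without WT GFP+ replicate 2). MHC class II genes, with Ciita at -0.97 (0.121 without WT GFP+ replicate 3 and 0.192 without Id2 KO GFP+ replicate 3), had 1 of 19 members higher and 2 lower (adjusted over the list alone, 1 and 4) (adjusted p = 0.258 with an estimated correlation; camera adjusted p = 0.319 without WT GFP+ replicate 3 and 0.183 without Id2 KO GFP+ replicate 3). DC transcription factors had 6 of 34 members higher and 2 lower (adjusted over the list alone, 8 and 3) (adjusted p = 0.258 with an estimated correlation; camera adjusted p = 0.351 without WT GFP+ replicate 2 and 0.0984 without Id2 KO GFP+ replicate 2). Interferon-stimulated genes (0.624), monocyte genes (0.421), erythroid genes (0.137) and T and NK genes (0.455) did not pass camera in Id2 KO against WT Zbtb46-GFP+ cells. The sex-linked list passed (0.0343 with an estimated correlation).

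In CDPs, neither targeted gene differed by the test, and the genes that did included sex-linked ones. Outside X and Y, the Batf3 KO CDPs had more Lipo3, a lipase-like gene, and more of the interferon-inducible genes Ifi205 and Ifi202b; the gap junction gene Gja1 was lower. Batf3 differed by -0.03 in Batf3 KO CDPs, and Id2 by -1.03 in Id2 KO CDPs (adjusted p = 1). In Batf3 KO CDPs limma called 10 genes (7 higher, 3 lower), 5 of them outside X and Y. These were Lipo3 at 2.86, Ifi205 at 2.33 (adjusted p = 0.0065; 0.0978 without WT CDP replicate 2, 0.114 without Batf3 KO CDP replicate 1 and 0.0891 without Batf3 KO CDP replicate 2), Olfr432 at 2.07 (0.0582 without WT CDP replicate 1, 0.0555 without WT CDP replicate 2 and 0.0921 without Batf3 KO CDP replicate 1), Ifi202b at 1.94 and Gja1 at -1.04 (0.0985 without WT CDP replicate 1, 0.242 without WT CDP replicate 2, 0.114 without Batf3 KO CDP replicate 1 and 0.327 without Batf3 KO CDP replicate 2). In Id2 KO CDPs it called 5 (4 higher, 1 lower), of which the autosomal gene was Lipo3 at 1.41 (adjusted p = 0.0455; 0.492 without WT CDP replicate 1, 0.0518 without WT CDP replicate 2, 0.628 without Id2 KO CDP replicate 1 and 0.145 without Id2 KO CDP replicate 2). The counts at an unadjusted p under 0.05 were 255 and 124. As designed on 15 arrays, limma called 0 genes in each (4 and 4 at an unadjusted p under 0.05), and with the 15-array term 5 and 0 (175 at an unadjusted p under 0.05 for Id2 KO). With the sets as a block, 25 genes were called in Batf3 KO CDPs. The sex-linked list passed in both (0.0112 and 0.00568 with an estimated correlation).

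Among other lists in CDPs, Batf3 KO cells had camera calls that an estimated correlation ended: pDC genes (median 0.41, adjusted p = 0.232 with an estimated correlation), cDC1 genes (0.381), cDC2 genes (0.381), interferon-stimulated genes (0.652) and stress genes (0.232; camera adjusted p = 0.0838 with the sets as a block), each higher. Neutrophil genes were lower (median -0.32, adjusted p = 0.496 with an estimated correlation). In Id2 KO CDPs the calls so ended were for neutrophil genes (median 0.44, adjusted p = 0.243 with an estimated correlation), monocyte genes (0.212), interferon-stimulated genes (0.595), cDC2 genes (0.595) and progenitor genes (0.255, lower; camera adjusted p = 0.0551 with the sets as a block). The pDC list did not pass in Id2 KO CDPs (adjusted p = 0.057), but did with the sets as a block (0.0133). Apart from the cDC1 list, where Ifi205 was higher in Batf3 KO, and the sex-linked list, no list had a called member in CDPs. With the sets as a block, the pDC member Ly6d was also called higher in Batf3 KO CDPs (1.08, limma adjusted p = 0.0258). The neutrophil median in Id2 KO CDPs was -0.16 without Id2 KO CDP replicate 1.

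Set directly against Batf3 KO Zbtb46-GFP+ cells, the Id2 KO cells had more Ly6d, Cdh1 and Nfil3, more Slamf6, a receptor of the SLAM family, and more Dab2, an endocytic adaptor. They had less Hpgd, Serpinb10, Ifi202b, Ifi205 and Tlr3. Host type is confounded with this comparison, as Id2 KO cells are labelled as from chimeric and Batf3 KO cells as from reporter mice. Id2 differed by -2.75 (SE 0.32, adjusted p = 0.00317) and Batf3 by 1.19 (adjusted p = 0.0163; 0.122 without Batf3 KO GFP+ replicate 2, 0.114 without Id2 KO GFP+ replicate 2 and 0.163 without Id2 KO GFP+ replicate 3). Cdh1 differed by 2.69 (adjusted p = 0.0571 with the 15-array term), Slamf6 by 2.50 and Nfil3 by 2.43. Hpgd differed by -2.71, Ifi202b by -2.13 and Tlr3 by -1.55. Ly6d differed by 2.87 (0.0841 without Batf3 KO GFP+ replicate 3, 0.12 without Id2 KO GFP+ replicate 2 and 0.0561 without Id2 KO GFP+ replicate 3), and Dab2 by 2.33 (0.23 without Batf3 KO GFP+ replicate 3, 0.297 without Id2 KO GFP+ replicate 2 and 0.0811 without Id2 KO GFP+ replicate 3). Serpinb10 differed by -2.53 (0.145 without Batf3 KO GFP+ replicate 2, 0.294 without Batf3 KO GFP+ replicate 3, 0.332 without Id2 KO GFP+ replicate 2 and 0.236 without Id2 KO GFP+ replicate 3). Ifi205 differed by -1.78 (0.145 without Batf3 KO GFP+ replicate 3, 0.159 without Id2 KO GFP+ replicate 2 and 0.105 without Id2 KO GFP+ replicate 3). The limma count was 117 (51 higher, 66 lower), 114 of them outside X and Y. It was 50 without Batf3 KO GFP+ replicate 2, 50 without replicate 3, 38 without Id2 KO GFP+ replicate 2 and 36 without replicate 3. With the sets as a block it was 506. For the 15 arrays as designed, limma gave 0 calls (12 at an unadjusted p under 0.05), and the 15-array term gave 101. Of 114 called genes outside X and Y, 25 had identical values in the replicate 1 pair, and of the 89 others, 88 differed in the same direction there (98.9%), against 53.7% of all untied genes. Over all 114 genes, with the 25 tied ones at 0, the median difference in that direction was 0.48 there and 1.22 on the 12 arrays.

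The pDC list was higher in Id2 KO than in Batf3 KO cells at the preset correlation, with 3 of 22 members higher and 0 lower (adjusted over the list alone, 12 and 1) and a median of 0.70 (adjusted p = 0.217 with an estimated correlation). Stress genes were lower, with Atf3 at -0.91 (0.239 without Batf3 KO GFP+ replicate 2, 0.343 without Id2 KO GFP+ replicate 2 and 0.293 without Id2 KO GFP+ replicate 3) and Btg2 at -0.85 (0.288 without Batf3 KO GFP+ replicate 2, 0.239 without Batf3 KO GFP+ replicate 3, 0.336 without Id2 KO GFP+ replicate 2 and 0.364 without Id2 KO GFP+ replicate 3), and kept their call (0.0319 with an estimated correlation). Neutrophil genes (median 0.74, adjusted p = 0.217 with an estimated correlation) and cell division genes (median 0.29, 0.217) were higher at the preset correlation, and interferon-stimulated genes lower (median -0.51, 0.269; camera adjusted p = 0.0815 without Batf3 KO GFP+ replicate 2). Progenitor genes (0.217 with an estimated correlation; camera adjusted p = 0.0636 without Batf3 KO GFP+ replicate 3) and DC transcription factors (0.307; 0.231 without Id2 KO GFP+ replicate 2) were higher, while MHC class II genes (0.287; 0.0501 without Batf3 KO GFP+ replicate 2 and 0.318 without Id2 KO GFP+ replicate 3) and T and NK genes (0.373; 0.15 without Batf3 KO GFP+ replicate 3 and 0.312 without Id2 KO GFP+ replicate 2) were lower. The cDC1 list had 1 of 23 members higher and 3 lower (adjusted over the list alone, 2 and 4) and did not pass camera (adjusted p = 0.115). The cDC2 (0.846), lymphoid (0.151), monocyte (0.846), erythroid (0.846) and sex-linked (0.119) lists did not pass.

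The genes lower in both knockouts included the cDC1 genes Xcr1, Tlr3, Gcsam and Snx22, with Ppt1, a lysosomal thioesterase, which kept their calls with each array left out. Clec9a changed by -1.01 in Batf3 KO (adjusted p = 0.0777 without WT GFP+ replicate 3, 0.129 without Batf3 KO GFP+ replicate 2 and 0.0833 without Batf3 KO GFP+ replicate 3) and -1.72 in Id2 KO. Rab7b changed by -1.49 in Batf3 KO (0.0891 without WT GFP+ replicate 3, 0.129 without Batf3 KO GFP+ replicate 2 and 0.0842 without Batf3 KO GFP+ replicate 3) and -2.77 in Id2 KO. Fzd1, a Wnt receptor, changed by -1.73 in Batf3 KO (0.091 without Batf3 KO GFP+ replicate 2 and 0.101 without Batf3 KO GFP+ replicate 3) and -1.63 in Id2 KO (0.076 without Id2 KO GFP+ replicate 3). Plpp1, a lipid phosphatase, changed by -1.81 in Batf3 KO (0.0845 without WT GFP+ replicate 3, 0.219 without Batf3 KO GFP+ replicate 2 and 0.219 without Batf3 KO GFP+ replicate 3) and -1.74 in Id2 KO (0.161 without Id2 KO GFP+ replicate 3). With the 15-array term Rab7b in Batf3 KO (adjusted p = 0.0794) and Fzd1 (0.502 and 0.186) and Plpp1 (0.316 and 0.086) in both lost their calls. Snx22 also lost its call with that term in both knockouts, as given above. Among genes higher in both, Igfbp4 changed by 1.00 in Batf3 KO (0.0757 without Batf3 KO GFP+ replicate 2) and 1.76 in Id2 KO, and Cd93 by 1.19 (0.148 without WT GFP+ replicate 2 and 0.329 without Batf3 KO GFP+ replicate 2) and 2.17. The lectin gene Cd209d changed by 2.07 in Batf3 KO (0.171 without WT GFP+ replicate 2, 0.113 without WT GFP+ replicate 3 and 0.379 without Batf3 KO GFP+ replicate 2) and 1.82 in Id2 KO (0.122 without WT GFP+ replicate 2, 0.0674 without WT GFP+ replicate 3 and 0.223 without Id2 KO GFP+ replicate 2). With the 15-array term Cd209d (0.257 and 0.0723) lost its call in both, and Igfbp4 (0.839), Cd93 (0.137) and Prtn3 (0.473) in Batf3 KO. In the replicate 1 arrays, Igfbp4 and Prtn3 in Batf3 KO, and Fzd1 in both knockouts, were tied with WT. A tie enters that fit as a difference of 0 and pulls the estimate towards 0, so these losses say little about the genes. On the 12 arrays, 49 genes passed in both comparisons with WT, 10 higher in both, 39 lower in both and 0 in opposite directions, and 42 lay outside X and Y. Independent lists would share 0.24 higher and 0.32 lower. Both comparisons use the same 2 WT Zbtb46-GFP+ arrays. Simulations with unchanged knockouts against the same WT arrays gave a mean of 0 and a maximum of 0 shared genes in 100 draws. Across genes, the log2 fold changes of the knockouts correlated at r = 0.65, against 0.50 in the simulations, with a covariance of 0.0477 against 0.0175; genes are not independent replicates. The WT arrays are too few to be divided between the comparisons, so part of the overlap may come from the shared controls. Both knockouts also had the opposite sex pattern to WT on these arrays, so a sex effect may add to the overlap. Simulations with unchanged knockouts hold no such difference. The overlap was 78 without WT GFP+ replicate 2, 24 without Batf3 KO GFP+ replicate 2, 23 without Batf3 KO GFP+ replicate 3 and 31 without Id2 KO GFP+ replicate 3, and 178 with the sets as a block. As designed on 15 arrays, limma gave an overlap of 0, with 11 genes for Batf3 KO and 37 for Id2 KO at an unadjusted p under 0.05.

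Whether a knockout acted differently in Zbtb46-GFP+ cells than in CDPs was tested as an interaction. For Batf3 KO, the cDC1 genes Gcsam, Snx22, Xcr1 and Tlr3, together with Gpr141b, Rasgrp3 and Cd36, had a larger fall in Zbtb46-GFP+ cells, as did Batf3. For Id2 KO, the same genes had a larger fall there, and Ly6d, Nfil3, Cd93 and Cdh1 a larger rise. In WT CDPs some of these genes already lay near their level in Batf3 KO Zbtb46-GFP+ cells, so that a fall would hardly show in CDPs: mean log2 signals were 4.92 and 5.89 for Gpr141b, 6.19 and 6.29 for Gcsam, and 5.77 and 6.20 for Xcr1. For Batf3 KO, Gpr141b differed by -4.71 (adjusted p = 9.47e-04) and Batf3 by -2.79 (adjusted p = 9.47e-04; 0.222 with the 15-array term). Xcr1 differed by -3.16 (adjusted p = 0.0211; 0.0965 without WT CDP replicate 1, 0.0658 without WT CDP replicate 2, 0.0514 without WT GFP+ replicate 3, 0.121 without Batf3 KO CDP replicate 1, 0.123 without Batf3 KO CDP replicate 2 and 0.0976 without Batf3 KO GFP+ replicate 2). The limma count was 19 (3 higher, 16 lower), and 12, all lower, with each array centred on its 75th percentile. It was 11 and 8 without WT CDP replicates 1 and 2, 41 and 10 without WT GFP+ replicates 2 and 3, 8 and 7 without Batf3 KO CDP replicates 1 and 2, and 10 and 11 without Batf3 KO GFP+ replicates 2 and 3. For Id2 KO, Tlr3 differed by -3.90 (adjusted p = 1.06e-05) and Gpr141b by -4.85 (adjusted p = 0.00118). Ly6d differed by 3.74 (adjusted p = 0.0197; 0.0656 without WT CDP replicate 1, 0.0727 without Id2 KO CDP replicate 2, 0.0987 without Id2 KO GFP+ replicate 2 and 0.0803 without Id2 KO GFP+ replicate 3) and Nfil3 by 2.60 (adjusted p = 0.0197; 0.0699 without WT CDP replicate 1, 0.0651 without Id2 KO CDP replicate 2, 0.0987 without Id2 KO GFP+ replicate 2 and 0.0779 without Id2 KO GFP+ replicate 3). Xcr1 differed by -3.14 (adjusted p = 0.0111; 0.0563 without WT CDP replicate 1, 0.0513 without Id2 KO GFP+ replicate 2 and 0.0779 without Id2 KO GFP+ replicate 3). Id2 itself did not pass (-2.10, adjusted p = 0.106; 0.0314 with the sets as a block). The count was 64 (23 higher, 41 lower), and 82 higher and 91 lower with quantile normalisation. It was 29 and 42 without WT CDP replicates 1 and 2, 37 without Id2 KO CDP replicate 1, and 24 and 21 without Id2 KO GFP+ replicates 2 and 3. As designed on 15 arrays, limma called 0 genes for either (3 and 5 at an unadjusted p under 0.05), and with the 15-array term 8 and 20. On the 12 arrays with the sets as a block the counts were 43 and 372.

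By list, the interaction of cDC1 genes was negative for both knockouts, which their lower expression in CDPs largely sets in advance. All 12 members called lower in Batf3 KO Zbtb46-GFP+ cells, and all 15 in Id2 KO, had a WT CDP level that left no room for at least 50% of the fall. The Batf3 KO interaction had 0 of 24 members higher and 6 lower (adjusted over the list alone, 0 and 17), with a camera adjusted p of 8.37e-58, or 0.00138 with an estimated correlation. The Id2 KO interaction had 1 of 24 members higher and 10 lower (adjusted over the list alone, 1 and 16), with a camera adjusted p of 6.27e-35, or 0.0063 with an estimated correlation. For Id2 KO, the interaction of the pDC list had 1 of 22 members higher and 0 lower (adjusted over the list alone, 12 and 0) (adjusted p = 0.0798 with an estimated correlation). Progenitor (0.0215 with an estimated correlation), lymphoid progenitor (0.0455) and stress genes (0.0215, lower) kept their calls. The neutrophil list had medians of 1.06 and 0.88 for Batf3 KO and Id2 KO, with adjusted p = 0.121 and 0.13 with an estimated correlation.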

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

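The tests of the pDC rise, of the neighbours of Batf3 and of sex or host type were chosen only after the result was seen; the counts over other splits of the arrays were planned.

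An interaction with stage cannot show an effect limited to Zbtb46-GFP+ cells where the WT CDP level leaves little room for a fall. In Batf3 KO this holds for Gpr141b, Rasgrp3, Cd36, Gcsam, Snx22, Xcr1, Batf3, Tlr3, Ppt1 and Fcrla, while Gatm, Hpgd, Cd209e and Tnfsf8 had room in CDPs. In Id2 KO it holds for the cDC1 genes called lower, as given above. Interactions with stage past the threshold drew attention to the following genes, as differences in log2 fold change between Zbtb46-GFP+ cells and CDPs. For Batf3 KO they were negative for Gpr141b at -4.71 (adjusted p = 9.47e-04), Rasgrp3 at -3.73 (adjusted p = 9.42e-04), Cd36 at -3.58 (adjusted p = 9.42e-04), Gcsam at -3.57 (adjusted p = 9.42e-04) and Snx22 at -3.33 (adjusted p = 9.47e-04). Xcr1 stood at -3.16 (adjusted p = 0.0211), Batf3 at -2.79 (adjusted p = 9.47e-04), Tlr3 at -2.32 (adjusted p = 9.42e-04), Gatm at -1.69 (adjusted p = 0.0229), Ppt1 at -1.97 (adjusted p = 0.00648) and Fcrla at -1.82 (adjusted p = 0.0211). Ifi205 stood at -2.90 (adjusted p = 0.0192), since it was higher in Batf3 KO CDPs. They were positive for Hpgd at 2.29 (adjusted p = 0.0479), Cd209e at 1.69 (adjusted p = 0.0341) and Tnfsf8 at 1.20 (adjusted p = 0.0406). Of these 15 genes, 7 kept the call with each array left out (Batf3, Gpr141b, Rasgrp3, Cd36, Gcsam, Snx22 and Tlr3), and 6 of the 15 kept it with the 15-array term. The adjusted p values of the others rose: Xcr1 (up to 0.123 without Batf3 KO CDP replicate 2), Gatm (up to 0.166 without Batf3 KO CDP replicate 1), Ifi205 (up to 0.121 without Batf3 KO CDP replicate 1), Hpgd (up to 0.29 without Batf3 KO CDP replicate 2), Cd209e (up to 0.243 without Batf3 KO CDP replicate 1), Tnfsf8 (up to 0.29 without Batf3 KO CDP replicate 2), Ppt1 (up to 0.0615 without Batf3 KO CDP replicate 2) and Fcrla (up to 0.136 without WT CDP replicate 2).

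For Id2 KO the difference was negative for Gpr141b at -4.85 (adjusted p = 0.00118), Tlr3 at -3.90 (adjusted p = 1.06e-05), Gcsam at -3.51 (adjusted p = 0.00118), Snx22 at -3.44 (adjusted p = 0.00118), Rasgrp3 at -3.38 (adjusted p = 0.00152) and Cd36 at -3.18 (adjusted p = 0.00154). Naaa, a lipid amidase, stood at -3.18 (adjusted p = 0.0368), Xcr1 at -3.14 (adjusted p = 0.0111) and Batf3 at -1.55 (adjusted p = 0.0318). Rab7b stood at -2.96 (adjusted p = 0.00167), Ppt1 at -1.88 (adjusted p = 0.00548) and Clec9a at -1.47 (adjusted p = 0.0111). It was positive for Ly6d at 3.74 (adjusted p = 0.0197), Nfil3 at 2.60 (adjusted p = 0.0197), Jchain, the joining chain of antibodies, at 2.42 (adjusted p = 0.0226), Cd93 at 2.33 (adjusted p = 0.0052) and Cdh1 at 2.25 (adjusted p = 0.00539). F13a1 stood at 1.63 (adjusted p = 0.0222), Igfbp4 at 1.80 (adjusted p = 0.00154) and Myb at 1.33 (adjusted p = 0.0226). Of these 20 genes, 11 kept the call with each array left out (Gpr141b, Tlr3, Gcsam, Snx22, Rasgrp3, Cd36, Cd93, Cdh1, Rab7b, Ppt1 and Igfbp4), and 9 of the 20 kept it with the 15-array term. The adjusted p values of the others rose: Batf3 (up to 0.168 without Id2 KO GFP+ replicate 2), Ly6d (up to 0.0987 without Id2 KO GFP+ replicate 2), Nfil3 (up to 0.0987 without Id2 KO GFP+ replicate 2), Jchain (up to 0.126 without Id2 KO GFP+ replicate 2), Naaa (up to 0.173 without Id2 KO GFP+ replicate 3), Xcr1 (up to 0.0779 without Id2 KO GFP+ replicate 3), Myb (up to 0.126 without Id2 KO GFP+ replicate 2), F13a1 (up to 0.124 without Id2 KO GFP+ replicate 2) and Clec9a (up to 0.0779 without Id2 KO GFP+ replicate 3).

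The rise of the pDC list in Id2 KO against WT Zbtb46-GFP+ cells could follow from a lower share of cDC1-lineage cells. In the simplest case that would raise other lineages alike. The median of 21 pDC members exceeded that of 24 cDC2 members by 0.96 (1.26 against 0.30). The 95% interval from the spread between arrays was 0.59 to 1.32. Permutation of members gave p = 0.001 (100000 permutations), treating members as independent. These lists did not rise alike, but a lower cDC1 share stays open. The effect of such a share on a gene would depend on that gene's level in the cells that remain. Neutrophil and granule genes rose as much as pDC genes (median 1.35), while the monocyte (-0.04), T and NK (-0.08) and erythroid (-0.10) medians lay near 0. A larger share of pDC-lineage and granulocyte-lineage cells stays open. Sex stays open. Against Batf3 KO cells, of the same sex pattern, the median was 0.70 (95% interval from the spread between arrays 0.18 to 1.23), where sex alone would give 0. Host type differs in that comparison, with Id2 KO cells from chimeric mice and Batf3 KO cells from reporter mice. But the list lost its call there with an estimated correlation (adjusted p = 0.217; fry 0.216), and its median was 0.55 in Batf3 KO against WT, which shares the sex difference, beside 1.27 in Id2 KO against WT. Mature pDCs among the sorted cells stay open too: 2 members (Irf7 at -0.22 and Pld4 at -0.34) lay below 0, but 0 of 11 members with a low baseline did. The gate for Zbtb46-GFP+ c-Kit-intermediate cells should leave out most mature pDCs and granulocytes, and the purity of the sort was not analysed here. An effect of Id2 loss on the progenitors is a hypothesis beside it, and the list's interaction with stage had adjusted p = 0.0798 with an estimated correlation.

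Some genes within 200 measured genes of Batf3 on chromosome 1, named its neighbours here, changed in Batf3 KO cells. DNA of another strain carried along with the targeted allele may be the source. Of 61 autosomal calls in either stage, Batf3 left out, 6 lay among its 235 neighbours (at most 200 measured genes to each side; two-sided Fisher exact p = 1.03e-04, odds ratio 8.96, 95% interval 3.12 to 21.1), while Id2 KO calls in that window gave p = 0.0723 and Id2 KO calls around Id2 p = 0.252. These counts describe the pattern and do not test its source, since the same calls raised the question. The Fisher test also treats genes as independent draws, and the window follows gene order, not distance along the chromosome. The 6 are given with their change in the stage where they were called and then in the other. They are Fcrla (-1.90 in Zbtb46-GFP+ cells, -0.08 in CDPs; adjusted p = 0.219 with the 15-array term), Itln1 (1.24 and 0.72) and Ifi203 (-1.24 and -0.31; 0.0763 without Batf3 KO GFP+ replicate 2 and 0.0619 without Batf3 KO GFP+ replicate 3). Ifi202b (1.96 and 1.94) and Olfr432 (1.51 and 2.07; adjusted p = 0.114 without WT GFP+ replicate 3 and 0.186 without Batf3 KO GFP+ replicate 2 in Zbtb46-GFP+ cells, 0.0582 without WT CDP replicate 1, 0.0555 without WT CDP replicate 2 and 0.0921 without Batf3 KO CDP replicate 1 in CDPs) passed in both stages. Ifi205 changed by 2.33 in CDPs (0.0978 without WT CDP replicate 2, 0.114 without Batf3 KO CDP replicate 1 and 0.0891 without Batf3 KO CDP replicate 2) and by -0.58 in Zbtb46-GFP+ cells (adjusted p = 1.00). A carried-along allele would act in both stages. For 3 of the 6 (Fcrla, Ifi203 and Ifi205) the WT level in the other stage left no room for at least 50% of the change. The other 3 shifted there by at least 50% as much in the same direction, which is too few genes to decide, so the strain explanation stays open. In CDPs the 3 called neighbours had a median of 2.07, while the interferon-stimulated list had a median of 0.14 (upper quartile 0.34) and 0 called members. No broad interferon response of the neighbours' size was seen there. The neighbours were picked by their change, so the gap between these medians is no test. A response limited to a few genes stays open in CDPs. In Zbtb46-GFP+ cells, with a list median of 0.50, an interferon response stays open.

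The genes outside X and Y that changed in Batf3 KO Zbtb46-GFP+ cells could reflect the sex or the host type of the mice, both confounded with genotype, and this stays open. Of the 60 genes, 43 (37 of them lower in Batf3 KO) had a WT CDP level that left no room for a shift of at least 50% of the change, so CDPs decide nothing for them. The other 17 (12 higher, 5 lower) had a median shift of 0.53 in CDPs (95% interval from the spread between arrays 0.39 to 0.67), in the direction seen in Zbtb46-GFP+ cells, where the median size was 1.56. Of these, 6 shifted by at least 50% as much in CDPs: Lipo3, Ifi202b, Olfr432, Stag3, Itln1 and Myof. Ifi202b, Olfr432 and Itln1 are neighbours of Batf3, for which carried-along strain DNA is another open source. An effect of sex or host type in Zbtb46-GFP+ cells alone was not tested. In the replicate 1 pair, whose WT and Batf3 KO arrays share the female pattern, 40 of 41 untied genes differed in the same direction (97.6%). Over all 60 genes, with the 19 tied ones at 0, the median was 0.34, against 1.499 on the 12 arrays. These values describe 1 array per genotype and are not a test.

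For each comparison between Zbtb46-GFP+ groups fitted as designed, the 6 arrays allow 10 splits, too few for a share under 0.05. All 10 of the 10 splits gave as many limma calls as the real one in Batf3 KO against WT (real 0, highest other 0), in Id2 KO against WT (real 0, highest other 0) and in Id2 KO against Batf3 KO (real 0, highest other 0). At an unadjusted p under 0.05 the real comparisons gave 11, 37 and 12 genes.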

How the results depend on the processing

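The fits on 12 arrays, with the term for the 3 arrays, with the 2 sets of arrays as a block and without genes on X and Y were chosen only after seeing the data; the other alternatives were planned. Counts follow the order WT, Batf3 KO and Id2 KO step, Batf3 KO and Id2 KO against WT in Zbtb46-GFP+ cells, the same in CDPs, Id2 KO against Batf3 KO, and the Batf3 and Id2 interactions. As designed on 15 arrays they were 1, 0, 0, 0, 0, 0, 0, 0, 0 and 0, on 12 arrays 2212, 1432, 1358, 67, 361, 10, 5, 117, 19 and 64 (overlap 49), and with the 15-array term 2679, 1918, 1917, 29, 206, 5, 0, 101, 8 and 20. With the sets as a block they were 4828, 3486, 3231, 249, 1211, 25, 6, 506, 43 and 372 on 12 arrays (overlap 178) and 4764, 3647, 3536, 48, 449, 6, 0, 183, 7 and 54 on 15. The steps' median over all genes shifted by -0.67, -0.70 and -0.69 as designed on 15 arrays, and by -1.04, -1.06 and -1.06 with the replicate block, as the 3 arrays have lower signal.

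For the fit as designed on 15 arrays, in the same order, array weights gave 1858, 2952, 1481, 111, 342, 16, 7, 304, 50 and 107. The weights had not converged when their estimation stopped. Quantile normalisation gave 909, 587, 543, 7, 46 and 3, then 11 for Id2 KO against Batf3 KO, 4 and 4 for the interactions and an overlap of 5. Centring on the 75th percentile gave 696, 456, 387, 6 and 36. The replicate block gave 25 and 3 for the WT and Batf3 KO steps, 1 and 2 for the knockouts in Zbtb46-GFP+ cells and an overlap of 1. With the compared groups alone, counts were 19, 2 and 2 for the steps, 1 for Id2 KO in Zbtb46-GFP+ cells, 11 and 4 in CDPs and 1 for Id2 KO against Batf3 KO. Trend and robust variance gave 0 for the WT step and 2 for Id2 KO in Zbtb46-GFP+ cells. The cause was not tested. With an array left out, the steps ranged from 0 to 13, 0 to 2 and 0 to 2, the knockouts in Zbtb46-GFP+ cells and the overlap from 0 to 1, and the others stayed at 0 (limma; the unadjusted counts stand beside each comparison).

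On 12 arrays, quantile normalisation gave 2348 and 2367 for the knockout steps, 117 and 670 for the knockouts in Zbtb46-GFP+ cells, 248 for Id2 KO against Batf3 KO, 173 for the Id2 interaction and an overlap of 88. A log2 change of at least 1 left 943, 647 and 613 in the steps and 237 in Id2 KO Zbtb46-GFP+ cells. The compared groups alone gave 35 for Batf3 KO in Zbtb46-GFP+ cells, 230 for Id2 KO against Batf3 KO and 12 for the Batf3 interaction, which was also 12 with the 75th percentile and 9 with all probe sets. All probe sets gave 9 for Id2 KO CDPs. Array weights gave 246 for Id2 KO against Batf3 KO, and the replicate block 555 for Id2 KO in Zbtb46-GFP+ cells and 120 for its interaction. Without genes on X and Y, limma called 5 in Batf3 KO and 0 in Id2 KO CDPs (124 at an unadjusted p under 0.05 with them in). The cause was not tested. With an array left out, counts ranged from 1180 to 1780, 638 to 826, 488 to 1108, 33 to 96, 120 to 304, 7 to 9, 4 to 5, 36 to 50, 7 to 41 and 21 to 91, and the overlap from 23 to 78.

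A result called in neither fit counts as alike or kept here, for genes and for lists. Of 499 results for named genes, 172 were alike as designed on 15 arrays, 323 lost the call and 4 reversed. That fit called 1 gene, Tlr3 in the WT step, so the rest of the 172 had no call in either fit. The reversed results were Vwf at -0.0391 in the WT step and Zbtb16 at -0.155 in the Batf3 KO step. In the Id2 KO step they were Bach2 at -0.307 and Nr4a1 at -0.135. All 4 are smaller in size than that fit's median shift. With the 15-array term 425 were alike and 73 lost the call, and with quantile normalisation 490 and 2. With the sets as a block on 12 arrays 474 were alike and 25 gained a call. Leaving out each array kept 1981 results and ended 335. Of 90 list results, 54 were alike with an estimated correlation and 36 lost the call, and 59 and 30 with fry. The neutrophil median in Id2 KO CDPs reversed to -0.159 without Id2 KO CDP replicate 1, with 1.13 as the highest, without replicate 2. No measure of background was used here, so signal over background was not given; the scale of the 3 arrays, with medians of 23.8 to 24.1, limits what they show.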

Other observations

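The test of expression kept from the CDP stage, the values of Kcnma1 and those of the basophil genes Mcpt8 and Prss34 were chosen only after the result was seen.

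The Id2 KO Zbtb46-GFP+ cells had higher levels of genes that CDPs express and that fall along the step, such as Cd93, Igfbp4, F13a1, Prtn3 and Myb, and lower levels of genes that rise along it, such as Tlr3, Xcr1 and Anpep. In Id2 KO against WT, Cd93 changed by 2.17 and Igfbp4 by 1.76, where the WT step changed them by -4.03 and -3.84. The WT arrays enter the Id2 KO comparison, so the step was read in the Batf3 KO. Of 205 autosomal genes higher in Id2 KO, 54 were called lower with stage there (26.3%) and 22 higher. Random gene sets, matched on mean level only, gave a median of 5.37% and at most 12.2% lower. By sign alone, 65.4% of the 205 were lower with stage. Of 133 lower genes, 81 rose with stage (60.9%) and 3 fell, where random sets gave at most 14.3%. By sign alone, 89.5% of the 133 rose. The random sets were not matched on spread, so the excess over them may overstate the link. Part of the Id2 KO difference may therefore be a less complete step from the CDP state; a different mixture of cells in the sort would give the same numbers.

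Kcnma1, a potassium channel gene, differed between replicates of WT and between the knockouts. It was not called in Id2 KO against Batf3 KO Zbtb46-GFP+ cells, where the spread used by the fit includes the WT arrays. Its log2 signal was 11.15 and 5.44 in WT CDP replicates 1 and 2, and 5.92 and 11.05 in WT GFP+ replicates 2 and 3. It was 5.57, 5.60, 5.34 and 5.64 on the 4 Batf3 KO arrays, and 13.10, 12.67, 13.24 and 12.82 on the 4 Id2 KO arrays. On the 3 arrays on another scale it was 3.31 in WT, 3.65 in Batf3 KO and 8.94 in Id2 KO. The basophil protease genes Mcpt8 and Prss34 measured 10.12 and 10.34 in Id2 KO GFP+ replicate 2 and 9.60 and 9.97 in replicate 3. In WT GFP+ replicates 2 and 3, Mcpt8 measured 6.01 and 7.95, and Prss34 7.09 and 9.004. In Batf3 KO GFP+ replicates 2 and 3, Mcpt8 measured 7.47 and 8.03, and Prss34 8.54 and 8.80. In CDP replicates 1 and 2, Mcpt8 measured 10.59 and 9.41 in Id2 KO, 8.69 and 8.93 in WT, and 8.32 and 8.95 in Batf3 KO. Prss34 measured 10.69 and 8.75 in Id2 KO CDPs, 6.83 and 8.59 in WT, and 6.68 and 8.68 in Batf3 KO. The 3 arrays on another scale decide nothing here, since most values were tied: Prss34 was 6.35 in each, and Mcpt8 6.79 in WT and Batf3 KO and 6.81 in Id2 KO.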
